A study of Caenorhabditis elegans with 2 samples.

How the data were processed

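The series measured where the nuclear hormone receptor NHR-25 sits on the genome of the nematode Caenorhabditis elegans. NHR-25 is the worm member of the NR5A family, to which fly FTZ-F1 and mammalian SF-1 belong. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on whole hermaphrodite worms at the L4 stage, the last larval stage. Per the labels, the strain OP33 carries an integrated transgene of NHR-25 with GFP and FLAG at its C terminus, an anti-GFP antibody was used, and chromatin was sheared by sonication. The samples are 2 biological replicates of 1 group. A control experiment is named in the labels, and no control file was used here.

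The deposited files are 8 peak lists in the 10-column narrowPeak layout. For each of the genome builds ce10 and ce11 there is a list for replicate 1, a list for replicate 2, a list for the pooled replicates and a thresholded list. Per the labels' names for these files, the first 3 were input for the irreproducible discovery rate (IDR) procedure and the last is its optimal output. The pooled list is named there as peaks and background. Its entries are all called peaks here, but they need not all be binding sites. Per the deposited text records, the thresholded list derives from both replicate lists and the pooled list of the same build. The peak caller, the aligner and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own deposited value. Its scale is not stated, so it was used only to rank and describe peaks within a list. The deposited −log10 q-value was at its highest value, 3.80, for all 1826 thresholded ce11 peaks and was not used to rank them. The other deposited column used is the summit offset of each peak, in bp from its start. Read counts are not in these lists, so the depth of each replicate is unknown. Intervals on shares of peaks cover counting error only.

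Genes, sequence and coordinates were used with ce11 alone. The reference was assembly WBcel235, which is ce11, with Ensembl release 115 genes. All ce11 peak ends lay within its chromosome lengths. It held 19985 protein-coding genes with 29326 distinct 5′ ends. Coordinates are printed counting from 1, and none were converted between builds.

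Replicates were compared by taking from each replicate list as many of the highest-signal peaks as there are thresholded peaks. An overlap of at least 1 bp counted as shared. The share was set against 1000 circular shifts of the peaks along each chromosome, for which the smallest two-sided permutation p is 0.002. Signals of the strongest overlapping peak of each replicate were correlated across thresholded peaks with 100000 permutations, for which the smallest p is 1e-05. Peaks are not independent replicates. The share of summits on chromosome X was compared with the share of protein-coding 5′ ends there by a two-sided exact binomial test. A summit within 500 bp of a protein-coding 5′ end was called promoter-proximal, and this share was set against 1000 circular shifts. The remaining summits were classed by annotation, with coding exons taking precedence over UTRs, introns and noncoding genes.

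The NR5A site YCAAGGYCR (Y is C or T, R is A or G) was searched on both strands within 100 bp of each summit. The same width was searched 500 bp away, on a side chosen by a fixed seed, or on the other side where that ran off the chromosome. The pair was compared by a two-sided exact McNemar test, and 14 motifs were tested with Benjamini-Hochberg adjustment. The trend with strength was tested by a permutation of Spearman's rho with 100000 resamples. A gene was called bound when it had the nearest protein-coding 5′ end to a thresholded summit, within 2 kb. Bound genes were tested in 20 gene lists by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. The odds ratios printed are sample odds ratios, with conditional exact 95% intervals. Of the heterochronic list, 5 microRNA genes were not matched by name among protein-coding genes and were not analysed here. A further 3 symbols, ram-4, nhr-75 and daf-21, matched no annotated protein-coding gene.

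Named genes followed a rule fixed before the data were examined, as were the lists, motifs, tests and most alternatives. The rule takes nhr-25, the genes at the 20 thresholded peaks of highest signal and up to 4 bound members of each list in order of signal. Because most of those 20 peaks proved to be mitochondrial, the 20 strongest nuclear peaks were added after the values were seen. Alternatives covered the overlap rule, window widths, site definition, background, gene assignment, build, peak threshold, merging of overlapping peaks and each replicate alone. Removal of mitochondrial peaks, removal of peaks near nhr-25 and restriction to autosomes were added after seeing the data.

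The procedures were tested on simulated data before use. All planted sites were found (100%), which was fixed in advance because the planted sequence always matches the searched site. With sites planted in 3% of windows, 100% of 20 simulations were called, against 0% with none planted. For gene lists, 98.8% of lists with 5-fold odds were recovered and 0.417% of unchanged lists were called. The lists given raised odds had 54 to 274 genes, so recovery in smaller lists was not tested. Binding was drawn independently for each gene, without peaks or their assignment to genes. A planted overlap of 39.4% was recovered as 41.1%. Shared peaks were moved by at most 100 bp, against a median width of 390 bp, so this recovery was largely set in advance. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.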

Results

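Binding of NHR-25 tagged with GFP was mapped in L4 worms in 2 biological replicates. The ce11 lists held 23929 peaks for replicate 1, 30000 for replicate 2, 30000 for the pooled data and 1826 after thresholding. The thresholded peaks were the 1826 pooled peaks of highest signal, with values from 30.3 to 1021 and a median of 41.2. Their median width was 390 bp. Read depth is unknown.

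The nhr-25 gene itself (WBGene00003623, chromosome X, 13008493 to 13013964, plus strand) held some of the strongest nuclear binding in the genome. Its 5 assigned peaks included the peaks ranked 4 and 5 among 1801 nuclear peaks. The number was 3 without replicate 1, 5 without replicate 2 and 2 with a 500 bp window. The stronger, at 13008105 to 13008508, had a summit 194 bp from the annotated 5′ end and a pooled signal of 248. Its signal was 61.1 in replicate 1 and 193 in replicate 2. The next, at 13008904 to 13009271, lay inside the gene, 153 bp from another of its 5′ ends, with a pooled signal of 221. An intronic peak at 13009675 to 13010064 had a signal of 106. Upstream, the intergenic peak at 13000959 to 13001089 reached 132 and ranked 21. In all, 13 thresholded summits lay in nhr-25 or within 20 kb of it, a stretch somewhat longer than 40 kb. With the gene and its promoter left out there were 8. The median was 1 per 40 kb window of chromosome X. None of the 13 had an NR5A site within 100 bp, and the gene with 20 kb on each side holds 0 such sites. The strain carries a transgene of this gene, so reads from the transgene and the native locus are not separated in these lists.

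**Figure D1:**
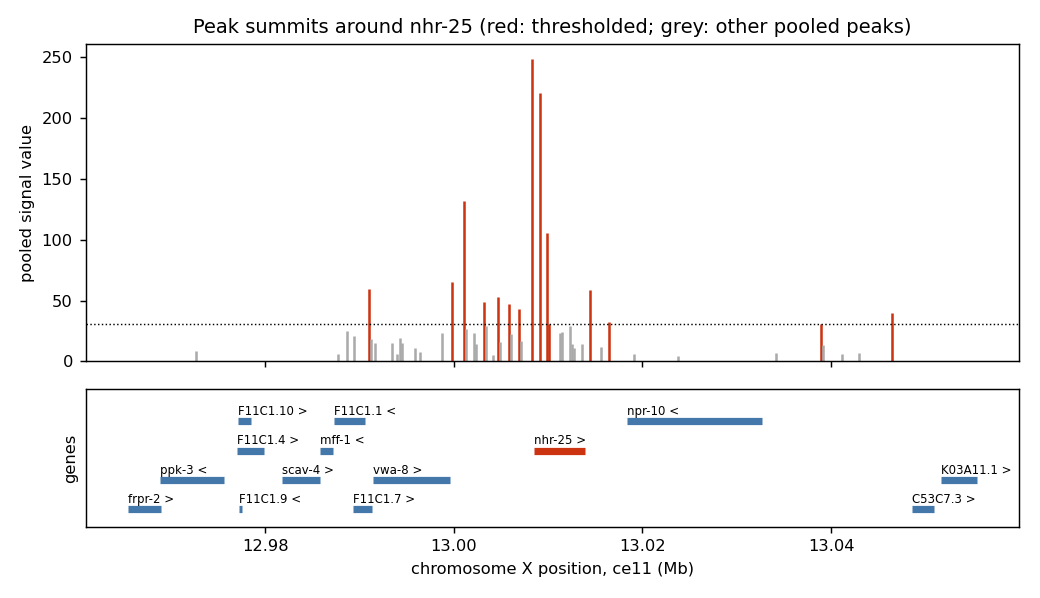
Pooled signal value of each peak summit (vertical lines) by ce11 position in Mb around nhr-25 on chromosome X, with thresholded peaks in red, other pooled peaks in grey, the lowest thresholded signal as a dotted line and protein-coding genes below (> plus strand, < minus strand). The tallest lines, at 248 and 221, stand at the 5′ ends of nhr-25.

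The strongest peaks in the data were mitochondrial. Of the 20 peaks of highest signal, 16 lay on the mitochondrial genome, including the 13 highest. The highest of all, at 12163 to 12574 in the coding sequence of MTCE.35 (WBGene00010967), had a signal of 1021, with 430 in replicate 1 and 604 in replicate 2. MTCE.21 (WBGene00000829) followed with 688. Inside COX3, a cytochrome oxidase subunit gene, peaks had signals of 488 and 355, the first nearest to the 5′ end of MTCE.25. A peak of 429 lay inside the rRNA gene MTCE.7, 219 bp from the 5′ end of ND1, an NADH dehydrogenase subunit gene. Peaks inside ND1 and ND6, another such gene, had 234.6 and 309. Together 25 thresholded peaks (1.37%) were mitochondrial, with a median signal of 301 against 41.1 for nuclear peaks.

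The 20 strongest nuclear peaks, a group chosen after its values were seen, included ribosomal protein genes, nhr-25 and 5 positions with no protein-coding 5′ end within 2 kb. The highest, at chromosome I 9382861 to 9383233 with a signal of 292, lay in an intron of ppfr-1, 6502 bp from the nearest protein-coding 5′ end. It overlapped the noncoding genes F16A11.7 and anr-20. The ribosomal protein gene rpl-3 (chromosome III, 3867436 to 3867741) followed with 267, 283 bp from its 5′ end, and tasp-1 (chromosome III, 10759102 to 10759384) with 261. The ribosomal protein genes rpl-35 and rpl-15 had peaks of 171 and 137. The chromatin regulators set-16, an MLL-type methyltransferase, and cbp-1, a CBP/p300 acetyltransferase, had peaks of 156 and 144, and set-16 had none without replicate 2. The genes hsp-3, an endoplasmic reticulum chaperone, cdc-48.1, a p97 ATPase, and sec-61.G, a translocon subunit, had 139, 136 and 140. Histone gene his-37 also had 136. The remaining assigned peaks were at serp-1.1 with 160, tag-340 with 145 at the noncoding gene F26F4.14, and F46H5.2 with 132. The peaks at 11094048 to 11094287 and at 9465809 to 9465949 on chromosome X, with 158 and 143, lay in intergenic sequence. Those at 6296467 to 6296698 on chromosome X, in an intron of mom-1, and at 12612478 to 12612867 on chromosome III, in an intron of Y111B2A.12, had 137 and 136. These 4 and the ppfr-1 peak had no protein-coding 5′ end within 2 kb.

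The replicates shared 55.1% or 54.2% of their strongest peaks, depending on direction, and their signals correlated weakly. The first is the share of the 1826 strongest of replicate 1 that overlapped the 1826 strongest of replicate 2, and the second is the converse. Circular shifts gave 2.52% ± 0.319 (SD, 1000 shifts) and 2.39% ± 0.310, with a permutation p of 0.002 each, the smallest they can give. Of the thresholded peaks, 67.3% overlapped the strongest of replicate 1 and 79.1% the strongest of replicate 2. The full lists, from which the thresholded list derives, held 98.5% and 99.7%. Across 1793 thresholded peaks the correlation of signals was positive (Spearman rho = 0.293, Pearson r of log2 signal = 0.420, permutation p of 1e-05 each, the smallest possible). Without the mitochondrial peaks, rho was 0.264 and r 0.293 (permutation p = 1e-05 each). Peaks were chosen on pooled signal, which narrows their range, and peaks are not independent replicates.

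**Figure D2:**
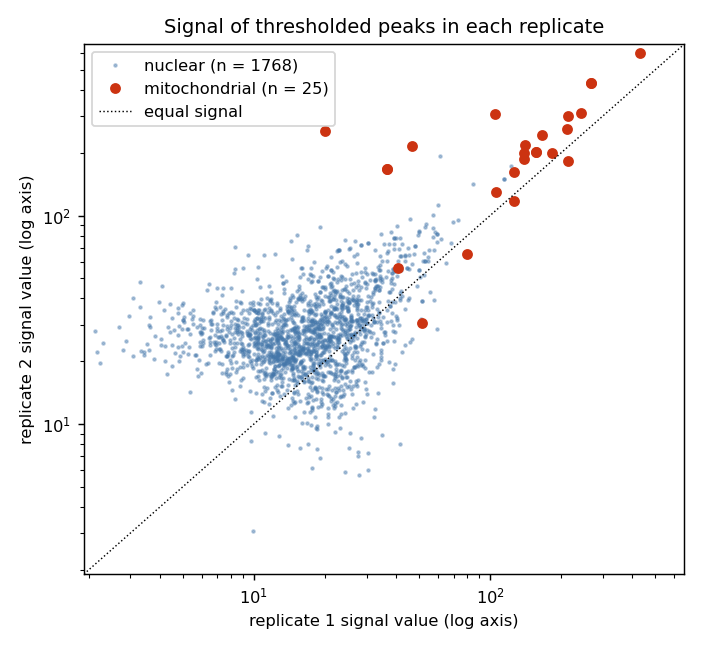
Signal value of the strongest overlapping peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for each of the 1793 thresholded peaks found in both, with 25 mitochondrial peaks in red and the dotted line marking equal values. Nuclear peaks form a broad cloud (Spearman rho of 0.264 among them), and mitochondrial peaks extend it to the highest values of both replicates.

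Binding was dense on chromosome X. It held 434 of the 1826 summits, 23.8% (Wilson 95% interval 21.9% to 25.8%), and 14.03% of protein-coding 5′ ends (two-sided exact binomial p = 1.4e-28). X makes up 17.7% of the genome's length, and held 17.99% of the pooled peaks below the threshold. The odds of lying on X were 1.42 times higher above the threshold than below it (Fisher exact p = 1.9e-09, a comparison added after the data were seen). Per megabase, X had 24.5 thresholded peaks, chromosome III 20.3 and chromosome V 12.9. The share was 20.9% among promoter-proximal nuclear summits and 26.7% among distal ones (Fisher exact p = 0.0046, odds ratio 0.725, a comparison added after the data were seen). X holds a smaller share of 5′ ends than of length, which by itself makes promoter-proximal summits rarer there. This test did not adjust for that density, so the difference is not shown to be one of binding. Peaks cluster, so the binomial test treats as independent some summits that are not.

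Summits gathered near 5′ ends and avoided coding sequence. Of 1826 summits, 814 (44.6%, Wilson interval 42.3% to 46.9%) lay within 500 bp of a protein-coding 5′ end, against 23.3% ± 1.05 in shifted positions (SD, permutation p = 0.002, the smallest possible). A larger promoter share lowers every other class, so the 1012 remaining summits were also compared with the remaining shifted positions, a comparison added after the data were seen. Of these, coding exons held 3.66% against 23.2% and introns 29.6% against 34.2%, each with a permutation p of 0.002. Intergenic sequence held 54.9% against 34.1%, and noncoding genes and pseudogenes 8.89% against 4.72% (permutation p = 0.002 each). UTRs held 2.87% against 3.73% (permutation p = 0.074).

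The NR5A site was enriched at summits and present in few of them. It lay within 100 bp of 63 summits (3.45%, Wilson interval 2.71% to 4.39%) and in 15 flanking windows (0.821%, interval 0.498% to 1.35%), with an exact McNemar p of 3.7e-08 and an adjusted p of 1.0e-07 over 14 motifs. The heterochronic gene hbl-1 had an intergenic peak with this site, 983 bp from its 5′ end. A peak assigned to the matrix gene let-653 also had it. That peak lay inside cutl-27, 1987 bp from the let-653 5′ end, and below the median signal. The strict form TCAAGGTCA was found at 0.931% against 0.219% (adjusted exact p = 0.010) and the nuclear receptor core AGGTCA at 12.4% against 6.08% (adjusted exact p = 2.1e-10). Other motifs were commoner. The repeat GAGAGAG was present at 20.6% of summits against 3.72% of flanks (adjusted exact p = 1.6e-56). The site GAGACGCAG, of the type bound by the zinc-finger protein EOR-1, was at 12.2% against 0.767% (adjusted exact p = 2.1e-49). The E-box CACGTG (8.38% against 3.83%, adjusted exact p = 3.8e-08) and the BLMP-1 site (2.52% against 0.712%, adjusted exact p = 2.6e-05) were also enriched.

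Some motifs were rarer at summits than in flanks. GATA sites were at 32.7% against 38.8%, TCF sites at 11.3% against 16.6% and Hox-TALE sites at 10.8% against 14.1% (adjusted exact p = 0.00023, 8.5e-06 and 0.0043). The GATA direction depended on the background: in dinucleotide-shuffled sequence the share was 30.2%, below that of summits, with TCF at 15.5% and Hox-TALE at 12.9%. Forkhead sites (5.42% against 7.12%, adjusted exact p = 0.050366) and ROR-type sites (0.110% against 0.493%, adjusted exact p = 0.076) did not pass. Both directions turned against shuffled sequence, where the shares were 4.44% and 0%. AP-1 sites (2.25% against 2.08%) and the GATA-like CTTATCA (3.94% against 3.89%) did not differ detectably from flanks, with adjusted exact p of 0.88 and 1.0. In shuffled sequence their shares were 3.23%, above that of summits, and 1.97%, below it.

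**Figure D3:**
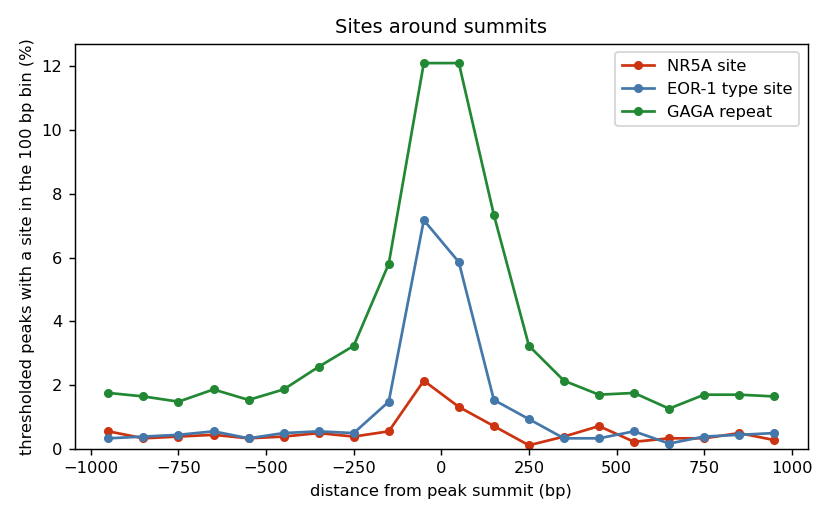
Percent of the 1826 thresholded peaks with a site in each 100 bp bin (vertical) by distance from the summit in bp (horizontal) for the NR5A site, the EOR-1 type site and the GAGA repeat. In the bin just before the summit the values are 2.14%, 7.17% and 12.1%.

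No trend in the NR5A site with peak strength was detectable. In 5 bins of rising signal, the site was at 2.19%, 4.38%, 4.66%, 3.56% and 2.47% of peaks. Spearman's rho between signal and the site was -0.0021 (two-sided permutation p = 0.93). The Wilson interval of the lowest bin, 1.11% to 4.25%, and that of the highest, 1.303% to 4.62%, overlap. The EOR-1 type site and the GAGA repeat rose weakly with signal, with rho of 0.060 and 0.052 (two-sided permutation p = 0.0098 and 0.027, unadjusted, in tests added after the data were seen).

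Heterochronic genes, which time larval cell fates, were bound almost as a group. Peaks were assigned to 1209 genes, 6.05% of the 19985 tested. Of 16 heterochronic genes, 13 were bound (odds ratio 68.0, 95% interval 18.6 to 372; adjusted Fisher exact p = 6.5e-13). The kinase gene kin-20 had 5 peaks with signals up to 75.8, of which 2 remained with a 500 bp window. With that window hbl-1, nhr-85, lin-41 and lin-42 had none, and lin-41 had none at 1 kb. The transcription factor gene hbl-1 had a peak of 74.6, the nuclear receptor gene nhr-85 3 peaks up to 73.2 and lin-41 a peak of 67.1. The others bound were mab-10 with 64.5, lin-66 with 59.1, lin-14 with 40.4, dre-1, lin-42, daf-12, blmp-1, lin-28 and apl-1. The last 6 had highest signals from 36.4 down to 32.9, near the lowest thresholded signal of 30.3. These and lin-14 lay under the median of 41.2. Unbound were lin-29, lin-46 and lep-2. In the strongest peaks of replicate 1 and replicate 2, 13 and 11 members were bound. The odds ratio was 35.0 without replicate 1, 18.3 with the peaks above the median signal, 24.97 with a 500 bp window and 29.2 against genes with any pooled peak. The bound number was 10.6 times that expected from draws matched on upstream distance.

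Ribosomal protein genes were the other large group, with 30 of 79 bound (odds ratio 9.72, 95% interval 5.93 to 15.7; adjusted Fisher exact p = 1.2e-15). Without replicate 2 the count was 22 of 79 and the odds ratio 6.37. It was 5.83 against genes with any pooled peak and 27.8 with every gene within 1 kb. Besides rpl-3, rpl-35 and rpl-15, rps-28 had a peak of 111. Heat shock and proteasome genes had 10 of 54 bound (odds ratio 3.55, interval 1.59 to 7.18; adjusted Fisher exact p = 0.0088). These included hsp-1 with 105, hsp-12.3 with 71.3 and the proteasome subunit gene rpn-3 with 50.7, besides hsp-3. This call was lost against genes with any pooled peak (odds ratio 2.16, adjusted Fisher exact p = 0.23). It was also lost with the peaks above the median signal, where fewer genes are bound (3.10, adjusted Fisher exact p = 0.19).

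Nuclear hormone receptor genes and lipid synthesis genes passed the test less firmly. Of 274 receptor genes, 30 were bound (odds ratio 1.93, interval 1.27 to 2.85; adjusted Fisher exact p = 0.0095). After nhr-25, the highest signals were at nhr-14 with 83.5, nhr-85 with 73.2 and nhr-91 with 66.4. Of 23 lipid synthesis genes, 5 were bound (odds ratio 4.33, interval 1.25 to 12.1; adjusted Fisher exact p = 0.043). These were the fatty acid synthase gene fasn-1 with 52.6, the desaturase gene fat-2 with 44.3, the acetyl-CoA carboxylase gene pod-2 with 38.5, the elongase gene elo-7 with 37.2, and elo-1. The receptor call held in 5 of 12 alternatives and the lipid call in 4 of 12. Against genes with any pooled peak their odds ratios were 1.64 and 3.34 (adjusted Fisher exact p = 0.14 and 0.18). The receptor call was lost without replicate 2 (odds ratio 1.57, adjusted exact p = 0.14) and on autosomes alone (1.54, adjusted exact p = 0.22). The lipid call was lost without replicate 1 (3.33, adjusted exact p = 0.13) and without replicate 2 (1.55, adjusted exact p = 0.49), with 4 and 2 genes bound. With draws matched on upstream distance it was lost as well (3.24 times the expected number, adjusted permutation p = 0.14). In the lists that passed, the NR5A site was sought at the strongest peak of each bound gene. It was at 1 of 13 heterochronic, 1 of 30 ribosomal and 0 of 10 heat shock and proteasome genes. Among receptor and lipid synthesis genes it was at 0 of 30 and 0 of 5. The share over all summits was 3.45%, so groups this small cannot show a lack of the site.

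Lists of cuticle, molting and epidermal genes did not pass. Of 176 collagen genes, 13 were bound (odds ratio 1.24, adjusted Fisher exact p = 0.57), with peaks of 75.7 at col-94, 54.9 at col-103, 54.4 at col-10 and 47.4 at col-39. Of 49 other matrix genes, 6 were bound (2.17, adjusted exact p = 0.23), among them noah-2 with 52.5, sym-1 with 49.6, let-4 with 43.4 and let-653 with 39.0. Of 29 molting genes, 4 were bound (2.49, adjusted exact p = 0.24). These were myrf-1 with 70.8, myrf-2 with 53.9, the receptor gene nhr-23 with 51.0 and lin-42 with 36.3. Of 24 epidermal regulators, 3 were bound (2.22, adjusted exact p = 0.29), namely let-413 with 63.5, nhr-23 and vab-10 with 33.6. Of 17 epidermal antimicrobial peptide genes, 3 were bound (3.33, adjusted exact p = 0.23), namely nlp-31 with 53.0, nlp-29 with 40.3 and cnc-8 with 35.9. Of 87 hedgehog-related genes, 2 were bound (0.364, adjusted exact p = 0.29), grl-4 with 36.6 and grd-3 with 35.3. The hedgehog odds ratio was 0.760 without replicate 1, where 4 genes were bound, and grl-4 had no peak with either replicate alone. The antimicrobial odds ratio was 2.17 without replicate 2, with 2 genes bound. Molting genes and epidermal regulators passed with the strongest peaks of replicate 2 alone (odds ratios 4.13 and 5.28, adjusted Fisher exact p = 0.021 and 0.012) and of replicate 1 alone (4.25 and 5.44, adjusted exact p = 0.023 and 0.010). Collagens passed with replicate 1 alone (1.98, adjusted exact p = 0.029). The peaks at col-94, let-4, noah-2 and let-413 lay 1785, 1793, 1320 and 1245 bp from the 5′ ends of these genes. The first was in an intron of dhc-4 and the second in an intron of C44H4.4. With a 1 kb window none of these genes had a peak.

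Signaling and tissue marker lists did not pass either. Bound were 2 of 27 vulva and uterus genes (lin-45 with 36.97, egl-17 with 33.8), 2 of 26 Wnt genes (mig-5 with 84.0, lit-1 with 55.6) and 2 of 10 Hox genes and cofactors (ceh-20 with 48.6, unc-62 with 37.001). Their odds ratios were 1.24, 1.29 and 3.89, with adjusted Fisher exact p of 0.75, 0.75 and 0.26. Without replicate 2 the Wnt odds ratio was 2.12, with 3 genes bound. The 8 of 85 pharynx list genes bound were pqn genes, named for glutamine- and asparagine-rich sequence, among them pqn-41 with 74.03, pqn-87 with 60.6, pqn-71 with 58.3 and pqn-21 with 47.2 (odds ratio 1.62, adjusted Fisher exact p = 0.29). Of 53 neuronal genes, snb-1, the synaptobrevin gene, was bound with 52.9 (0.298, adjusted Fisher exact p = 0.57). Of 52 germline genes, spe-9 with 37.6 and msp-65 with 34.3 were bound (0.621, adjusted Fisher exact p = 0.81), and none without replicate 2. No bound gene was found among 15 somatic gonad, 23 intestine and 18 body wall muscle genes, with adjusted Fisher exact p of 1.0, 0.57 and 0.75 and upper odds limits of 4.33, 2.70 and 3.53. Without replicate 2, 1 of the muscle genes was bound (odds ratio 0.955).

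**Figure D4:**
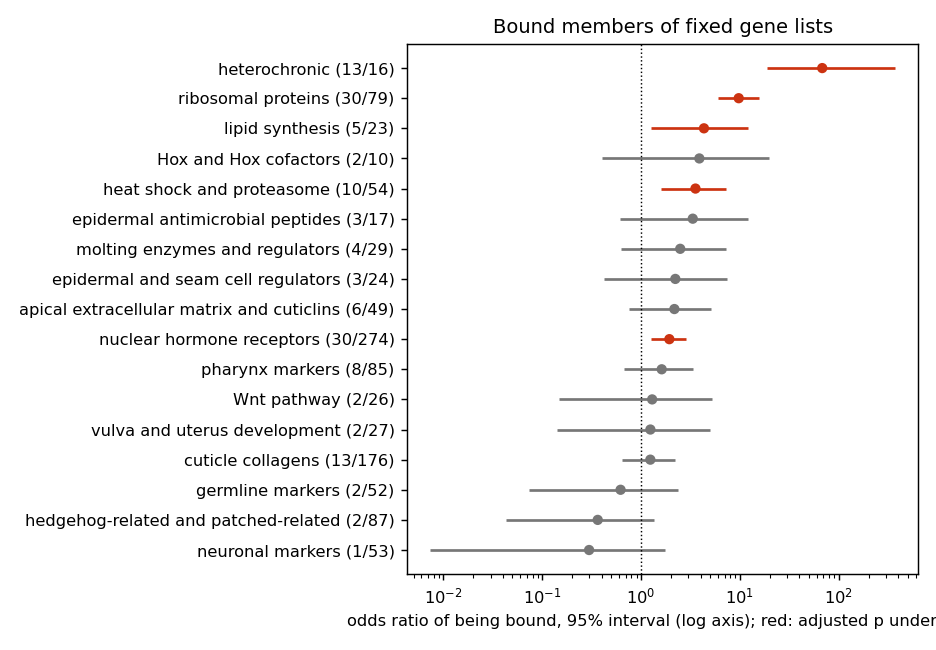
Odds ratio of being bound (points, log axis) with its 95% interval (lines) for the fixed lists with at least 1 bound gene, labelled with bound over tested genes, and red where the adjusted Fisher exact p passed 0.05. Heterochronic genes (68.0) and ribosomal protein genes (9.72) stand apart from the dotted line at 1.

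The builds gave nearly the same number of peaks. The thresholded list held 1792 peaks on ce10, a ratio of 0.981 to ce11. By chromosome the ratio ran from 0.970 on X to 1.0 on the mitochondrial genome. Median signals were 41.5 and 41.2.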

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

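Removal of mitochondrial peaks, removal of peaks near nhr-25 and restriction to autosomes were chosen after seeing the data; the other alternatives were set before. Replicate overlap stayed above its shifts, from 43.1% with summits within 100 bp to 54.97% on ce10, and signal correlation past its test, with rho from 0.263 to 0.298. The chromosome X share (22.3% to 24.1%) and the promoter share (23.5% at 200 bp to 58.7% at 1000 bp) kept direction and side of the test under every alternative run, as did the NR5A share (0.931% to 12.4%). With each replicate alone, the X share was 23.2% to 24.0%, the promoter share 42.2% to 42.9% and the NR5A share 2.79% to 3.18%. The strength trend passed in no alternative. Its rho was -0.043 to -0.014 with each replicate alone and turned positive with TCAAGGTCA (0.0055) and without mitochondrial peaks (0.0023), with two-sided permutation p of 0.82 and 0.92. The number of enriched lists, 5, fell to 3 with a 1 kb window, 3 with a 500 bp window and 3 with every gene within 1 kb. It fell to 2 against genes with a pooled peak and 2 with the peaks above the median signal. Windows and thresholds reduce the bound genes; otherwise the cause was not tested. It was 4 with matched draws, 4 on autosomes and 6 with either replicate alone. The heterochronic and ribosomal calls held in 12 of 12 alternatives. The ratio of builds was 1.0 for the pooled lists, which hold 30000 peaks each, so their lengths carry no information on agreement.

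Some list odds ratios that had not passed crossed 1 without passing. With a 1 kb window these were collagens (0.929) and matrix genes (0.830), and with every gene within 1 kb the same lists (0.977 and 0.623). With a 500 bp window, epidermal regulators and Hox genes were at 0. Against genes with a pooled peak, vulva genes were at 0.740, Wnt genes at 0.634 and germline genes at 1.11. With matched draws, where the value is bound over expected number and not an odds ratio, vulva genes were at 0.972. Their odds ratio was 0 with the peaks above the median signal and 0.607 to 1.3 with each replicate alone. On autosomes, matrix genes were at 0.967 and vulva genes at 0.828. The cause was not tested. Of 72 named genes, 65 were bound with a 1 kb window, 48 with 500 bp, 58 with the peaks above the median signal, and 70 and 64 with replicate 2 and replicate 1 alone. Peak numbers moved over 1.5-fold at 9 and 14 of them, mostly down. None was assigned to grl-4 with either alone, to lin-45 with replicate 2, or to set-16, vab-10, fat-2, elo-7, cnc-8, spe-9 and msp-65 with replicate 1. For set-16 a strong replicate 1 peak was present but was not assigned to that gene. With a 1 kb window no peak was assigned to col-94, noah-2, let-4, lin-41, let-413, fat-2 or pqn-41. No paired analysis was possible because there is 1 group. Replicate overlap and correlation have no value without a replicate. Read depth is unknown, so its effect on peak number was not measured.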

Other observations

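Gene families defined by symbol prefix were scanned after the data were seen, over 94 families of at least 20 genes with two-sided Fisher exact tests. Besides ribosomal protein and nhr genes, the lin family had 15 of 47 members bound (odds ratio 7.36, adjusted exact p = 2.7e-06), some of which are in the heterochronic list. Also bound more often were the ztf zinc-finger genes (7 of 25, odds ratio 6.07, adjusted exact p = 0.0072) and the dpy genes (7 of 25, with the same values), which included dpy-30 and dpy-27. Of the chemoreceptor families, str, srh and srw were bound less often and the others scanned did not pass. None of 193 str genes, 1 of 220 srh genes and none of 109 srw genes was bound (adjusted exact p = 0.00025, 0.00047 and 0.020). The clec genes had 4 of 240 bound and the fbxa genes 2 of 170 (adjusted exact p = 0.019 and 0.027).

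Small RNA genes also lay near summits, in a scan of 6 classes chosen after the data were seen. A nuclear thresholded summit lay within 500 bp of 65 of 346 snoRNA genes against 5.97 ± 2.51 in circular shifts (SD), 86 of 612 tRNA genes against 11.9 ± 3.99, 19 of 129 snRNA genes against 2.05 ± 1.60 and 24 of 261 microRNA genes against 4.84 ± 2.55. Each had an adjusted permutation p of 0.0024. The piRNA genes, which lie in clusters, had fewer, 94 of 15363 against 224 ± 37.7 (adjusted permutation p = 0.0024), and none of 20 rRNA genes had a summit in reach, against 0.253 ± 0.584 (adjusted permutation p = 1.0). Genes with several peaks included din-1 with 6 and nurf-1, lit-1 and mak-1 with 5 each. Without replicate 1 these numbers were 5, 3, 3 and 4, with the peaks above the median signal 4, 3, 2 and 2, and with a 500 bp window 1, 4, 3 and 1.

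Technical and other explanations were weighed for 3 patterns. All 3 patterns were picked after the data were seen; the tests of mitochondrial read depth and both nhr-25 tests were also chosen after values were seen. The 3 GAGA and EOR-1 tests were set after the motif shares at summits and flanks had been seen, though before their own values. The design has 1 group, so no biological difference between groups was tested.

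Mitochondrial peaks were the strongest. High mitochondrial read depth may account for them. They covered 52.5% of the 13794 bp genome, just past the 50% set for this test, and the replicate lists held 28 and 27. Coverage follows from the number and width of the peaks, which had been seen, and does not measure depth. This test therefore does not decide. The test of receptor binding was void: 0 of 25 summits had an NR5A site in reach, but the mitochondrial genome holds 0 such sites, which fixed that count. Binding at this form of site has no place there, and binding through other sequence stays open.

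At nhr-25, extra copies of the transgene could raise the whole neighbourhood. The 20 kb on each side, nhr-25 and its promoter left out, held 30 pooled peaks with a median signal of 20.3, above that of 98.1% of 442 windows of 40 kb on X, while their number was above that of 93.7%. The excess was uneven, with 25 peaks upstream (median 21.2) and 5 downstream (median 11.9) against a median of 8.23 over windows, so a binding-rich upstream region stays open as well. The site test was void here too: 0 of 13 summits within 20 kb had an NR5A site in reach, but the locus holds 0 such sites, so binding through other sequence stays open.

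GAGA and EOR-1 type sites were at more summits than NR5A sites. Such a site was at 3.40% of 1826 unpeaked promoter-proximal positions against 24.6% of 796 promoter-proximal summits, a ratio of 0.138. Sequence shared by promoters without a peak is therefore argued against as the cause. Positions overlapping a peak of any list were left out, so the comparison does not cover promoters that gather reads. Reads gathering on the repeat GAGAGAG do not account for all EOR-1 type sites. These were at 9.52% of 1449 summits without that repeat in reach and 0.483% of their flanks (exact McNemar p = 2.0e-33). Shorter or interrupted GA stretches were not removed, and this cause was not tested for the GAGA repeat itself. Promoters open to many factors may still be involved: NR5A sites were at 2.72% of 515 nuclear summits with a GAGA or EOR-1 type site and 3.81% of 1286 without (odds ratio 0.705, Fisher exact p = 0.32), which does not decide. Against promoters as the place, summits with such a site were promoter-proximal less often, 38.1% against 46.7% (odds ratio 0.702, Fisher exact p = 0.00094, a test added after the data were seen), while open elements elsewhere stay possible.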
